A study of Mus musculus with 4 samples.

How the data were processed

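RNA was measured on 4 Affymetrix arrays in double-positive thymocytes, the immature T cells of the thymus that carry both CD4 and CD8. Per the labels, the cells came from female C3H/HeN mice aged 4 weeks and were sorted with microbeads. They were cultured for 3 h in 3 ml at 5.0E+06 cells per ml, with 1e-07 M dexamethasone, a synthetic glucocorticoid, or with medium and 0.1% PBS. Each group had 2 arrays, and the series design describes these as technical replicate extracts. The p-values therefore measure the spread between these extracts. Whether the extracts came from separate wells or from a common pool of cells is not stated.

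The deposited values are intensities on a linear scale, made with MAS5 per the submitters' processing notes, which give no version or settings. MAS5 summarises the probes of each probe set into a signal. The values themselves showed a trimmed mean, with 2% cut from each end, between 100.06 and 100.07 on every array, so all arrays share a global scaling. No detection calls were used. The table held 12488 probe sets, of which 66 were controls, and 0 columns of other samples. Of the remaining probe sets, 10833 named 1 gene in the platform annotation, 396 named several and 1193 named none. The gene ID of 10817 of the single-gene probe sets matched the reference gene table, and 0 were renamed. No coordinates are given, since the array names no genome build. The reference table, of assembly GRCm38.p6, served only for names and for which genes neighbour each other.

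Signals were used as log2(signal + 1), where 1 is the 10th percentile of all values, rounded. Fold changes are on this scale, which understates the change of dim genes. Each of 8251 genes was represented by its brightest probe set over all arrays, and genes with a mean log2 signal at or under the 40th percentile were left out, which left 5582. Dexamethasone was compared with medium using lmFit and eBayes with a trend on mean signal in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is said to have risen, fallen or changed only when it passed this threshold. Probe sets for bacterial and yeast transcripts, taken from their low values as not added to the sample, reached at most 14 (19 probe sets, median 1.85). A group with both values at or under 14 was treated as background, and a fold against it is given as a lower bound, computed against 14. The number of arrays limits the precision.

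Before the data were examined, 30 gene lists, the alternatives and the rule for named genes were fixed. The rule took the 12 largest rises and 12 largest falls among genes that passed with non-overlapping groups, every measured member of the pro- and anti-apoptotic Bcl-2 family lists, and the 3 largest changes among passing members of each other list. Where no member passed, it took the 2 members with the largest difference, as values. It also took Nr3c1, Tsc22d3, Fkbp5, Per1, Cd4 and Cd8a. Passing list members outside this rule that are named below were chosen after their values were seen. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, two-sided, and adjusted over the 29 lists tested. The same lists were tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move, on balance, in a common direction and compares them with no other genes.

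The fit was tested on simulated data for the 5582 genes, in 10 draws with 200 changed genes each. It called 28.8% of genes changed by 0.5 on the log2 scale, 70.9% of those changed by 1 and 91.5% of those changed by 2. Unchanged genes made up 4.14% of the calls. A list shifted by 0.5 was called in 10 of 10 draws, and 0 of 200 unshifted lists were called. The simulation drew genes and arrays independently, with the spread that the fit itself assumes. It cannot show how correlated genes, shifts between arrays or technical extracts affect the calls. The alternatives were 3 other scalings, 2 other pseudocounts, 2 other filters, a fit without the trend, a replicate block, the mean of a gene's probe sets, probe sets in place of genes, the other list tests and leaving out each array. A pseudocount of 16 and scaling to the hybridization controls were added after the data were seen.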

Results

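The series title asks how dexamethasone alters pro- and anti-apoptotic molecules in double-positive thymocytes. Median signals were 21.7 and 21.1 on the medium arrays and 22.8 and 21.9 on the dexamethasone arrays, and 55.6% to 57.2% of probe sets lay above the background of 14. The Pearson correlation of log2 signals across probe sets, which are not independent replicates, was 0.988 between the medium arrays, 0.983 between the dexamethasone arrays and 0.975 to 0.979 between groups. The ratio of the 3′ to the 5′ actin control, a measure of RNA integrity, was 1.15 and 1.06 in medium and 1.40 and 1.24 with dexamethasone. For Gapdh it was 0.838 and 0.845 in medium and 0.904 and 0.823 with dexamethasone, which did not separate the groups. The 9 hybridization control probe sets, bacterial and phage transcripts added before hybridization, were on average 1.37-fold higher on the dexamethasone arrays. Directions below are relative to the deposited scaling. Scaling to these controls would move the median log2 difference of all genes from 0.00 to -0.46.

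Dexamethasone strongly raised a small set of genes within 3 h. The largest fitted rise among the tested genes was that of Usp18, which removes the ubiquitin-like protein ISG15 from its targets. Its signal was 5.20 ± 2.55 in medium and 117 ± 18.1 with dexamethasone (mean ± SD, n = 2), at least 8.38-fold higher. Tnfsf11, which encodes the cytokine RANKL, and Gpr65, a proton-sensing receptor, also started from background and rose at least 3.28-fold and at least 3.56-fold. Eipr1, which takes part in endosomal sorting, rose from 83.5 ± 4.45 to 693 ± 15.4, a log2 difference of 3.04 ± 0.08 (SE). Ppp1r21 rose 4.60-fold, Mfhas1 4.34-fold, and Zfp36l2, which promotes decay of AU-rich mRNAs, 3.57-fold. Trgv1, a T cell receptor gamma variable segment, rose 2.98-fold from a signal of 28.2. The Actb probe set that rose 2.92-fold belongs to a family-wide design and was dim, at 38.4 in medium. The actin control probe sets, with signals of 3221 or more in medium, differed by 0.04 to 0.29 on the log2 scale, and another dim Actb probe set by 0.80, without passing.

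The largest fall was that of Id3, an inhibitor of E-protein transcription factors, from 321 ± 8.34 to 64.7 ± 7.50, a log2 difference of -2.30 ± 0.11. Phlda1, a pleckstrin-homology protein linked to cell death, fell with a log2 difference of -2.11 ± 0.17. Myoz1, Smtn and Irs2, the last an adaptor of the insulin receptor, fell into background with dexamethasone and were at least 1.69-fold, 2.82-fold and 1.55-fold lower. The transcription factors Runx1 and Klf3 were 2.44-fold and 2.12-fold lower. Ccnd3, which encodes the D-type cyclin D3, fell from 781 ± 15.3 to 362 ± 19.7. Bysl, Cldn4, Car2 and Mmp12 completed the 12 largest falls, with log2 differences of -1.26, -1.15, -1.14 and -1.08.

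In all, 218 of 5582 genes changed (3.91%), of which 105 rose and 113 fell, with a median absolute log2 difference of 0.67 among them. At least 2-fold changes numbered 45, with 32 rises and 13 falls, against 14 and 187 with scaling to the hybridization controls. The chance values that follow treat the 4 arrays as independent, which technical extracts need not be. An excess over them can therefore arise without an effect of dexamethasone. At an unadjusted p under 0.05 in limma there were 1111 genes, against 279.1 expected by chance. Groups did not overlap for 50.5% of genes, against 33.3% by chance. These counts come from limma and rest on all 4 arrays: leaving out any array gave 32 to 78 changed genes and 25 to 39 at least 2-fold changes. A fit without the variance trend called 19 genes.

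**Figure D1:**
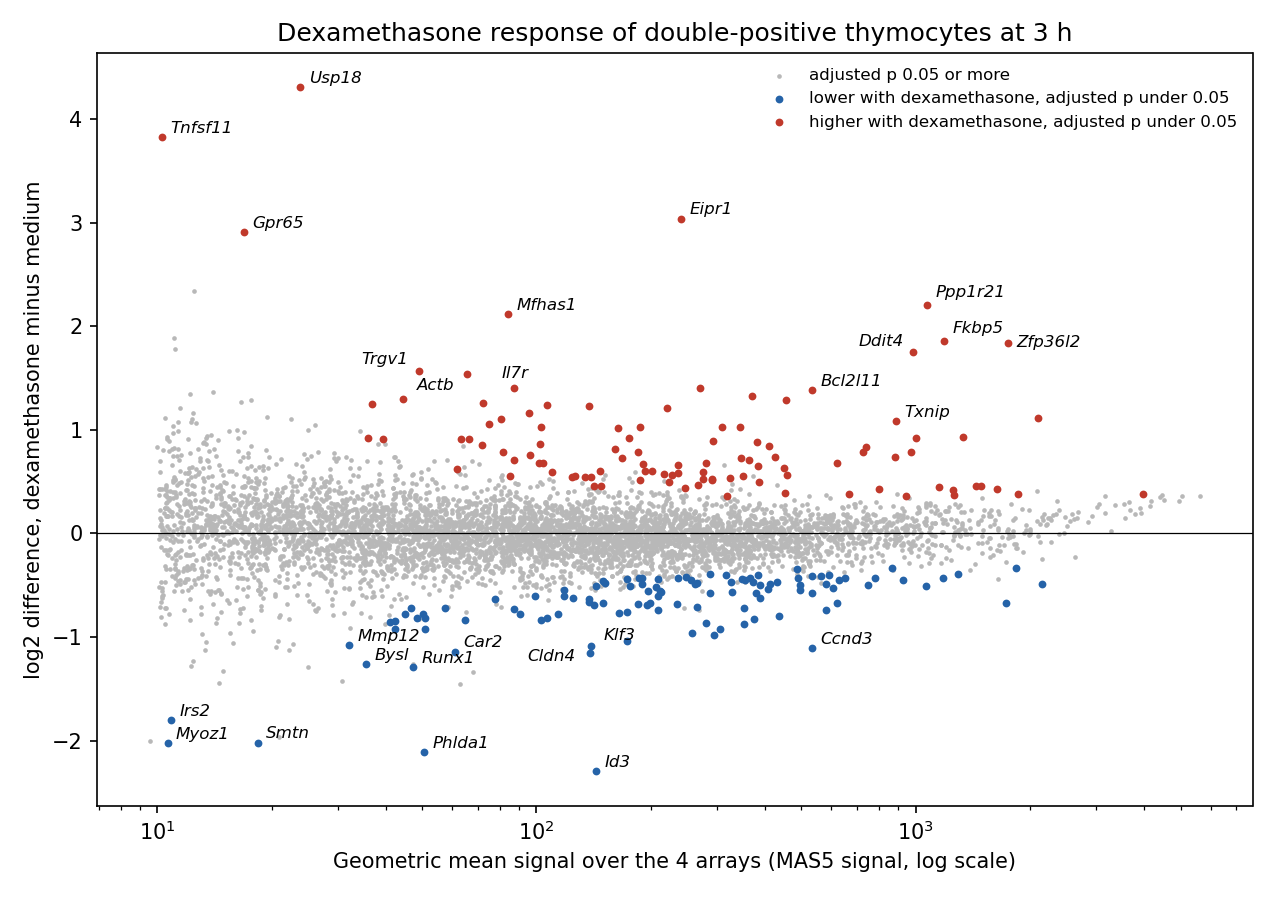
Each dot is a gene, placed by its geometric mean MAS5 signal over the 4 arrays (log axis) and its log2 difference, dexamethasone minus medium at the deposited scaling; coloured dots are the 105 genes that rose and the 113 that fell. Usp18, Tnfsf11 and Gpr65 lie high at low signal, while Eipr1 (3.04) and Id3 (-2.30) stand apart at higher signal, and with scaling to the hybridization controls 13 of the coloured genes switch sign.

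Known targets of the glucocorticoid receptor were higher as a list. Of 20 measured, 5 rose and 0 fell, and 7 rose when adjusted over the list alone. Fkbp5, a co-chaperone of the receptor, rose from 625 ± 49.6 to 2267 ± 162, a log2 difference of 1.86 ± 0.08. Ddit4, an inhibitor of mTORC1, rose 3.37-fold and Il7r, the interleukin-7 receptor alpha chain, 2.64-fold. Txnip, an inhibitor of thioredoxin, rose 2.12-fold on its brighter probe set and was at 39.2 in medium and 39.1 with dexamethasone on the dimmer. Nr3c1, the receptor gene itself, rose 1.90-fold from 25.8 (limma adjusted p = 0.0371), a call lost when any array was left out. Per1 had a log2 difference of 0.40 ± 0.24 and did not pass. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at background in both groups and was not tested. The list passed camera upwards (adjusted p = 3.74e-06), and 17 of its 20 members were higher at the deposited scaling. The call was lost at adjusted p = 0.742 with an estimated correlation. With scaling to the hybridization controls 4 rose and 3 fell, beside 41 and 2512 of all 5582 genes. The list's mean log2 difference was then 0.02 against 0.48. This scaling shifts every gene alike. The list then passed camera upwards against the other genes (adjusted p = 1.21e-10). That call cannot tell a response of this list from the shift and is no separate support.

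Among the regulators of apoptosis, Bcl2l11 stood out. It encodes Bim, a BH3-only protein that promotes cell death, and rose from 330 ± 11 to 865 ± 21.3, a log2 difference of 1.39 ± 0.07 (limma adjusted p = 0.000351). The other Bcl2l11 probe sets had log2 differences of 0.44 and 1.30. At the deposited scaling it was the only measured member of the pro-apoptotic Bcl-2 family to pass, 1 of 8 and also 1 when adjusted over the list alone. The list held 16 genes, 7 of which had no probe set that names 1 gene. Its unmeasured members, among them Bax, Bbc3 and Pmaip1, cannot be judged here. The log2 differences were 0.36 for Bid, 0.31 for Bok, 0.15 for Bik, 0.04 for Bnip3, -0.05 for Bcl2l13, -0.12 for Bad and -0.15 for Bak1.

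Of 26 listed anti-apoptotic Bcl-2 family members and other survival proteins, 18 were measured. Of these 18, 0 passed at the deposited scaling, over all genes and adjusted over the list alone. With scaling to the hybridization controls 10 of the 18 fell, as did 3 of the 8 pro-apoptotic genes (Bak1, Bad and Bcl2l13), while Bcl2l11 still rose. Over all genes 2512 of 5582 fell with this scaling, which shifts every gene alike, so these counts are not particular to apoptosis genes. Closest at the deposited scaling was Bcl2l1, which encodes Bcl-xL, with a signal of 666 ± 96.4 in medium and 476 ± 5.59 with dexamethasone (log2 difference -0.47 ± 0.10, limma adjusted p = 0.0629). It was lower and past the threshold in 4 of 15 alternatives, among them centring on array medians (adjusted p = 0.0482), the stricter filter (adjusted p = 0.0460) and scaling to the hybridization controls (-0.93), with adjusted p from 8.44e-06 to 0.236 over the 15. Bcl2 was at 44.0 ± 0.354 in medium and 63.6 ± 2.97 with dexamethasone (0.52 ± 0.13, limma adjusted p = 0.0887). Mcl1 differed by -0.04 ± 0.09. Bcl2l2 had a log2 difference of 0.79 ± 0.41 near background. The remaining members of this list lay between -0.41 for Pim2 and 0.26 for Api5, with Akt1 at -0.28, Birc3 at -0.24, Cflar at -0.22, Bag1 at -0.16, Pim1 at -0.13, Birc5 at -0.04, Akt2 at -0.03, Birc6 at 0.05, Dad1 at 0.08, Xiap at 0.09, Bcl2l10 at 0.20 and Birc2 at 0.26.

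**Figure D2:**
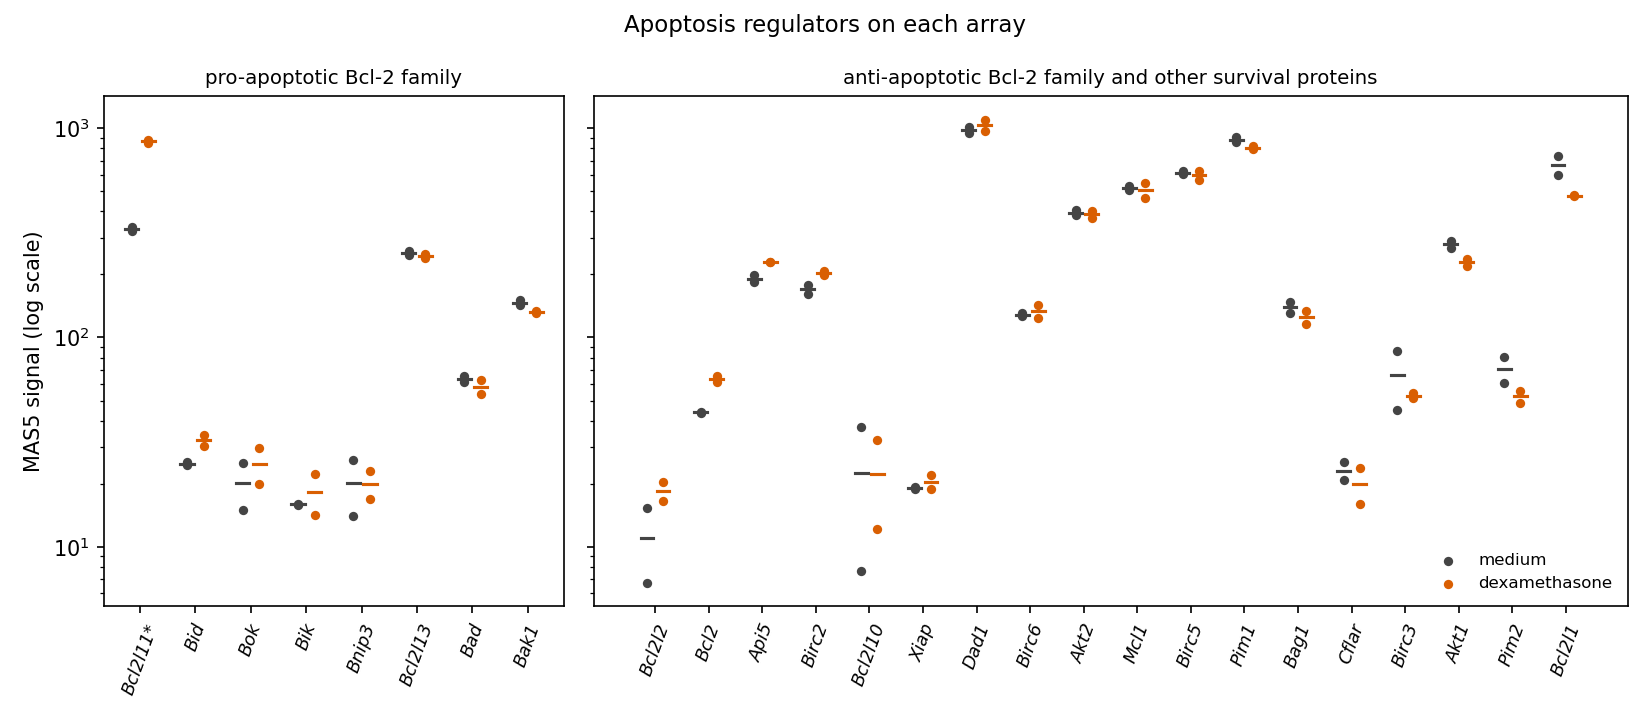
Signals (MAS5, log axis) of the 8 pro-apoptotic and 18 anti-apoptotic or survival genes on each array, with medium in grey, dexamethasone in orange, dots for the 2 arrays and a bar for their mean; an asterisk marks a gene that passed the test at the deposited scaling. Bcl2l11, at 330 in medium and 865 with dexamethasone, is the only gene with an asterisk. With scaling to the hybridization controls 10 survival genes and 3 pro-apoptotic genes would be lower past the threshold, beside 2512 of all 5582 genes.

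Caspases, apoptosome components and apoptotic nucleases gave 0 passing genes of 12 measured and 24 listed, also when adjusted over the list alone. The largest log2 differences were 0.33 ± 0.33 for Endog and 0.23 ± 0.10 for Htra2. Of 17 death receptors and adaptors, Tnfaip3, which encodes the NF-kappaB inhibitor A20, rose 2.04-fold, while the adaptor Traf4 fell (-0.96 ± 0.09, against -0.33 on its other probe set) and the costimulatory receptor Cd27 fell (-0.45 ± 0.07). Adjusted over the list alone, 1 rose and 4 fell. In the p53 pathway 0 of 14 genes passed and 1 rose when adjusted over the list alone. Gadd45a was at 0.50 ± 0.11 and Ccng1 at 0.41 ± 0.13. Among 14 NF-kappaB family members and targets, Tnfaip3 rose and Nfkbib, an inhibitor of NF-kappaB, fell (-0.45 ± 0.08), with 1 rise and 3 falls when adjusted over the list alone. These lists did not pass camera. Closest were the death receptors and adaptors, of which 13 of 17 were lower at the deposited scaling (camera adjusted p = 0.0887).

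Genes of the double-positive programme changed in both directions at the deposited scaling. Of 30 measured, 2 rose and 6 fell, and 3 rose and 7 fell when adjusted over the list alone. Runx1 fell most, followed by Ptcra, which encodes the pre-T cell receptor alpha chain (-0.84 ± 0.12), the transcription factor Ets2 (-0.79 ± 0.07) and the receptor Notch1 (-0.68). Cd52 and Cd8b1 fell with log2 differences of -0.45 and -0.33. The chromatin organiser Satb1 (0.43, but -0.03 with scaling to the hybridization controls) and the transcription factor Ikzf1 (0.68) rose. Of the other coreceptor genes, Cd4 differed by -0.06 ± 0.10 and Cd8a by 0.00 ± 0.07, and neither passed, but with scaling to the hybridization controls both fell (-0.51 and -0.45). The list did not pass camera (adjusted p = 0.806). With scaling to the hybridization controls 0 rose and 20 fell, beside 2512 of all 5582 genes that fell. The list then passed camera downwards (adjusted p = 0.0216), the range over 17 alternatives being 0.0216 to 0.980. This scaling shifts every gene alike, so that call cannot tell a response of this list from the shift.

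Immediate-early and T cell receptor-induced genes were lower as a group. Of 19 measured, 3 fell and 1 rose, and 4 fell and 1 rose when adjusted over the list alone. Besides Id3, the falls were those of Zfp36 (-0.83 ± 0.10) and Zfp36l1 (-0.77 ± 0.15), both of which encode proteins that promote mRNA decay. Dusp2, a phosphatase of MAP kinases, rose 1.90-fold. With scaling to the hybridization controls 0 rose and 12 of the 19 fell, beside 2512 of all 5582 genes. At the deposited scaling the list passed camera downwards (adjusted p = 0.0467), and this was lost at adjusted p = 0.742 with an estimated correlation. Without the second medium array the adjusted p was 0.160 and without the second dexamethasone array 0.246, within a range of 0.00920 to 0.742 over 17 alternatives.

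Of 36 genes of the T cell receptor complex and its proximal signalling, 4 rose and 2 fell, or 5 rose and 5 fell when adjusted over the list alone. Ctla4, an inhibitory receptor, rose 1.88-fold and Ptpn22, a phosphatase that restrains receptor signalling, 1.78-fold. Nfatc3 (0.56) and Cd2 (0.47) also rose. Socs1, an inhibitor of cytokine signalling, fell from 2188 ± 159 to 1372 ± 77.4, and the kinase gene Fyn fell by 0.52 on the log2 scale. Among 19 cytokine and chemokine receptors, Il7r rose and Il4ra, the interleukin-4 receptor alpha chain, fell (-0.71 ± 0.08), or 1 rose and 3 fell when adjusted over the list alone.

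Cholesterol and fatty acid synthesis genes were lower as a list. Of 17 measured, 16 were lower with dexamethasone, 4 fell over all genes and 11 fell when adjusted over the list alone. Sqle, the squalene epoxidase of sterol synthesis, fell from 420 ± 5.30 to 221 ± 17.5, a log2 difference of -0.93 ± 0.08. Dhcr7, which completes cholesterol synthesis, Hmgcs1, which makes its precursor HMG-CoA, and Fdps, the farnesyl diphosphate synthase, fell with log2 differences of -0.78, -0.73 and -0.67. The list passed camera (adjusted p = 7.72e-07), with a median log2 difference of -0.35, and was lost at adjusted p = 0.742 with an estimated correlation. In the fit without the variance trend 0 of its genes fell, beside 2 of all 5582 genes. With scaling to the hybridization controls 16 fell, beside 2512 of all genes.

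Other metabolic lists held few changes. In glycolysis and glucose uptake, the lactate transporter gene Slc16a1 fell (-0.77 ± 0.15), 1 of 17 measured, and 1 rose and 1 fell when adjusted over the list alone. In oxidative phosphorylation 0 of 34 genes passed either way, also when adjusted over the list alone, and the largest log2 differences were -0.41 for Cox5b and 0.34 for Atp5pb. Of 28 genes of oxidative stress and glutathione, Txnip rose and the thioredoxin reductase gene Txnrd1 fell (-0.69 ± 0.11), with the same counts when adjusted over the list alone. Of 11 genes of sphingolipid metabolism, Ugcg, which converts ceramide to glucosylceramide, fell (-0.48 ± 0.07), and 2 rose and 1 fell when adjusted over the list alone.

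Genes for cytosolic ribosomal proteins were slightly higher as a list at the deposited scaling, with a median log2 difference of 0.23, but the list's mean was -0.00 after quantile normalization and -0.29 with scaling to the hybridization controls. Of 18 measured, 0 passed over all genes and 7 rose when adjusted over the list alone. With a replicate block 8 rose and 1 fell, beside 169 and 184 of all 5582 genes. With scaling to the hybridization controls 0 rose and 7 fell, beside 41 and 2512 of all genes. Rpl41 was at 0.37 ± 0.11 and Rps19 at -0.44 ± 0.25. The list passed camera (adjusted p = 0.000268), and this was lost at adjusted p = 0.742 with an estimated correlation and at 0.865 after quantile normalization, the range over 17 alternatives being 8.71e-06 to 0.889. Other bright genes were also higher: lists matched on signal had a median of 0.18.

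Of 32 Myc-linked genes of ribosome biogenesis, the nucleolin gene Ncl rose (0.37 ± 0.06, but -0.08 with scaling to the hybridization controls), and 3 rose when adjusted over the list alone. Among 40 genes of the cell cycle and DNA replication only Ccnd3 passed, and 2 rose and 4 fell when adjusted over the list alone. Fkbp5 was the only one of 25 heat shock and folding genes to pass, with 2 rises when adjusted over the list alone. Herpud1, a component of degradation at the endoplasmic reticulum, rose 2.03-fold, 1 of 18 genes of the unfolded protein and amino-acid stress response and 1 when adjusted over the list alone. Of 30 proteasome and ubiquitin genes, Psma6 rose (0.38 ± 0.06, but -0.07 with scaling to the hybridization controls), also 1 when adjusted over the list alone.

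In the interferon response list, 3 of 20 genes rose, and 6 rose and 5 fell when adjusted over the list alone. Besides Usp18 these were the DNA sensor gene Ifi204, 1.82-fold, and the peptide transporter gene Tap2 (0.38 ± 0.07, but -0.08 with scaling to the hybridization controls). Of 34 genes of adhesion, migration and the cytoskeleton, Actb rose on its dim probe set and Tagln2 fell (-0.40 ± 0.07), with 3 rises and 3 falls when adjusted over the list alone.

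The lists of markers for other cells that such a sort could hold included Cldn4 and Car2, both among the 12 largest falls. None of the 5 marker lists tested passed camera with the main settings. Ptcra is also in the double-positive list and Il7r among the receptor targets. A change in a marker therefore cannot tell other cells from a response of the sorted cells. Of the 6 markers measured for mature single-positive thymocytes, Il7r rose, with 2 rises and 1 fall when adjusted over the list alone. Of 8 for double-negative thymocytes, Ptcra and the transcription factor gene Gfi1 (-0.76 ± 0.08) fell, with the same counts when adjusted over the list alone. This list passed with the stricter filter, at the 60th percentile, which left 5 genes (adjusted p = 0.0381), the range over 17 alternatives being 0.0381 to 0.852. Among 10 B cell markers, Ighm, the immunoglobulin mu heavy chain, rose from 1270 ± 17.7 to 1750 ± 1.77, a log2 difference of 0.46 that was 0.01 with scaling to the hybridization controls, with 1 rise and 1 fall when adjusted over the list alone. Among 15 markers of macrophages, granulocytes and dendritic cells, H2-Ab1 fell from 57.2 ± 6.01 to 31.4 ± 0.778, with 4 falls when adjusted over the list alone. In this list 12 of 15 members were lower at the deposited scaling (camera adjusted p = 0.0887), and it passed without the filter on dim genes (adjusted p = 0.0338), the range over 17 alternatives being 0.0338 to 0.742. Cldn4 fell among 5 markers of stroma and epithelium, with 1 rise and 1 fall when adjusted over the list alone. Car2 fell among 4 erythroid markers, too few to test as a list, and 1 fell when adjusted over the list alone.

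**Figure D3:**
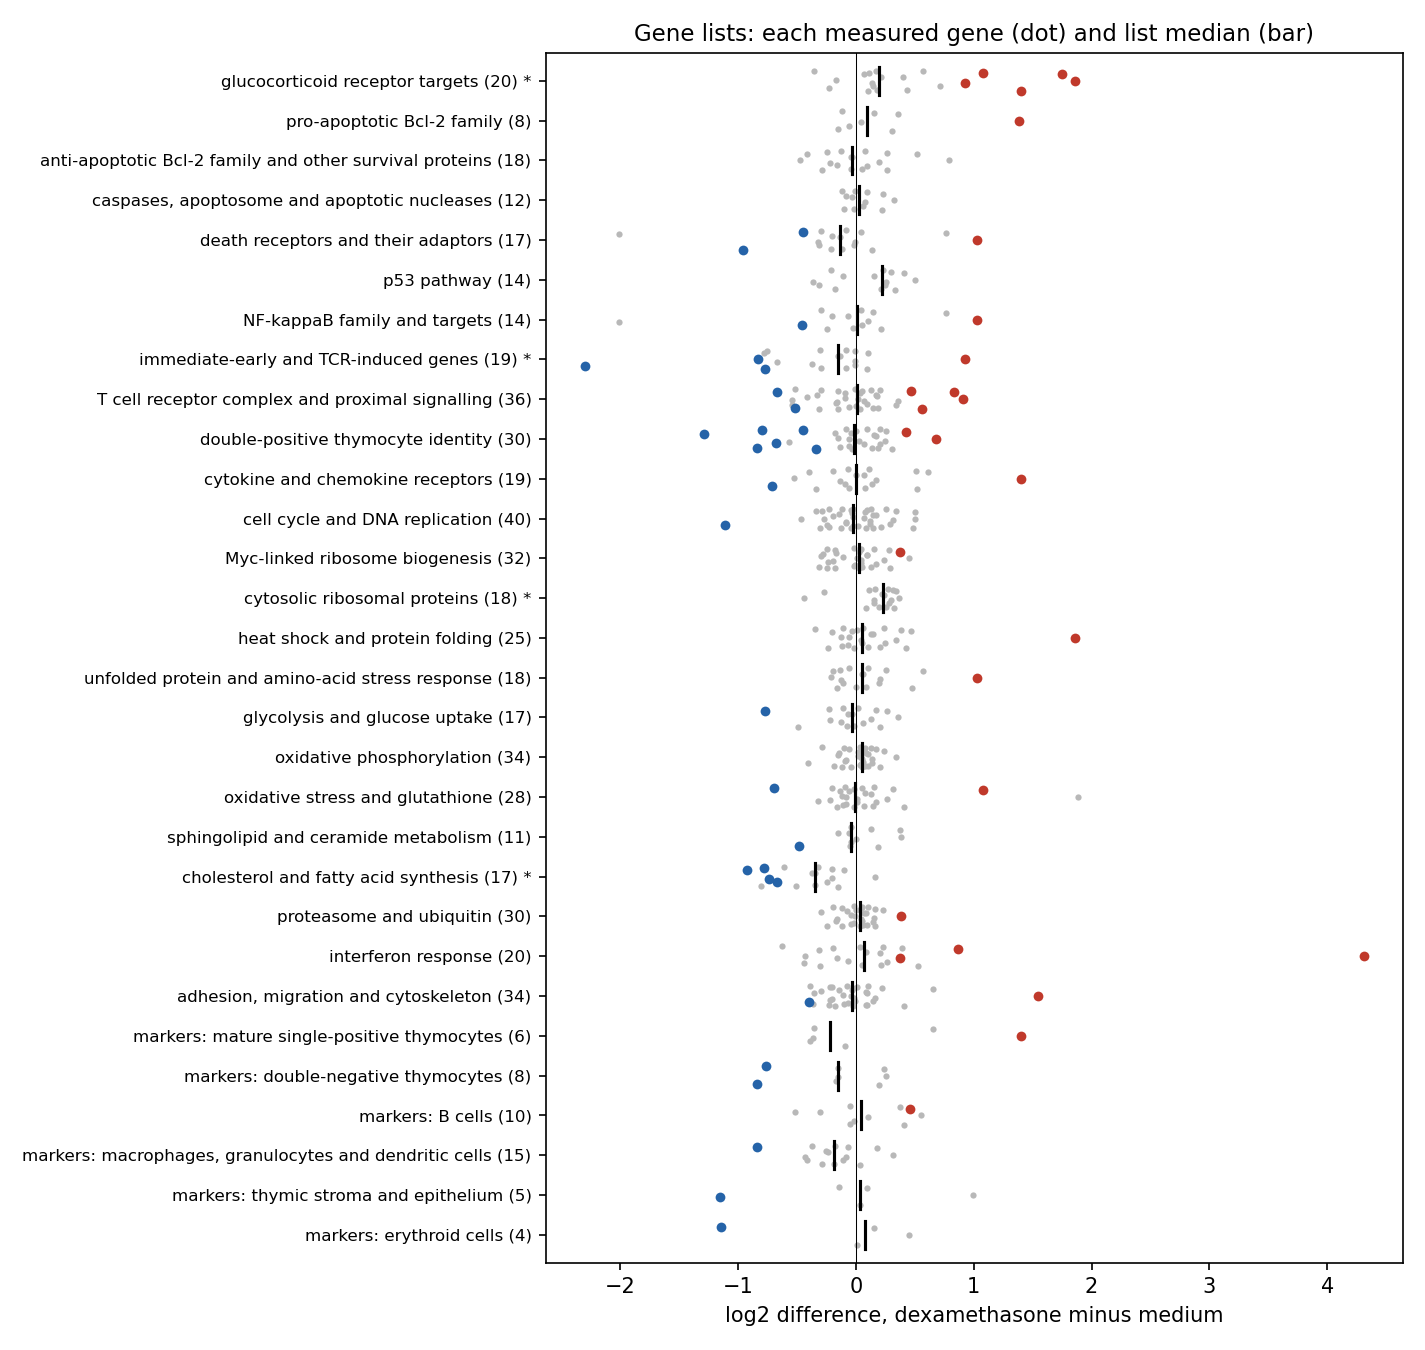
Log2 differences at the deposited scaling, dexamethasone minus medium, of every measured gene of the 30 lists (dots; red rose, blue fell, grey did not pass), with the list median as a bar, the number measured in parentheses and an asterisk for the 4 lists past camera. The glucocorticoid receptor targets extend to the right and the cholesterol and fatty acid genes to the left of 0, while the ribosomal list, with its median at 0.23, has a mean of -0.29 with scaling to the hybridization controls.

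Camera called 4 of 29 lists, and the other 25 had adjusted p from 0.0887 to 0.898. With an estimated correlation 0 lists passed (lowest adjusted p = 0.742), and with fry 0 passed (lowest adjusted p = 0.0883). The former test rests on 2 residual degrees of freedom, so calls lost with it decide nothing about correlation between genes. The immediate-early list lost its call although its estimated correlation was -0.04 (unadjusted camera p = 0.0977 against 0.00644). The median, mean and test differed in sign for 8 lists, none of which passed: the anti-apoptotic genes, NF-kappaB, T cell receptor signalling, cytokine receptors, oxidative stress, sphingolipids, and the markers of mature thymocytes and of stroma. Of the 54 named genes that passed, 10 also passed in each of the 14 or 15 alternatives run for single genes, namely Usp18, Tnfsf11, Eipr1, Gpr65, Ppp1r21, Fkbp5, Zfp36l2, Ddit4, Id3 and Bcl2l11. Scaling to the hybridization controls also ended the calls of Dusp2, Ctla4, Ptpn22, Ifi204 and Nr3c1.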

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

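The tests of less labelled RNA, of interferon and of a defect on an array, and scaling to the hybridization controls, were chosen only after the result was seen.

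The hybridization controls BioB, BioC, BioDn and CreX, which the comparison of genes does not use, were higher on both dexamethasone arrays than on both medium arrays for 9 of 9 probe sets. Their mean log2 difference was 0.457, with a range of 0.32 to 0.62, while the arrays of a group differed by 0.17 in medium and 0.19 with dexamethasone. A distortion that depends on brightness is argued against at these signals by the 50 mouse genes nearest in signal to each control. Their median difference was taken for each of the 9 controls. The median of these 9 values was 7.18e-05, and the highest, 0.176, lay below the lowest control. Less labelled mouse RNA on the dexamethasone arrays, from whatever cause, cannot be told apart from a difference in the amount of control added, since the deposited values keep no record of either amount. The controls are added before hybridization, so they do not measure mRNA per cell. If the controls set the scale, 2512 genes would have lower signals past the threshold and 41 higher ones.

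The ribosomal protein list was higher at the deposited scaling with a median of 0.23. A shift shared by bright genes may account for it, since 9.82% of 10000 lists matched on signal had a median at least as high. Scaling is the other open explanation: after quantile normalization the list's median was 0.0333 and its camera adjusted p 0.865, within a range of 8.71e-06 to 0.889 over 17 alternatives. A response of the bright genes themselves to dexamethasone was not tested and stays open.

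Usp18, an interferon-induced gene, showed the largest fitted rise among the tested genes, which leave out probe sets that name no single gene. Interferon in the dexamethasone cultures is argued against as a 2-fold rise shared by interferon-induced genes: of 8 others chosen, the 4 above the filter (Ifit2, Isg15, Irf7 and Irf9) had a mean log2 difference of -0.15 with an upper 95% bound over genes of 0.542. The other 4 (Ifit1, Ifit3, Mx1 and Mx2) were under the background of 14 in both groups and decide nothing. Their log2 differences were 0.84, 0.92, 0.15 and 0.20. Over all 8 genes the mean was 0.19, with an upper 95% bound over genes of 0.636. Both bounds take genes as independent. Ifi204 and Tap2 of the wider list rose, by 0.87 and 0.38 on the log2 scale. A defect on a single array is argued against as well, because the lower dexamethasone value was 7.46 times the background of 14, which both medium values lay under. Whether the probe set measures another transcript cannot be told, since the array holds 1 Usp18 probe set, and a direct response to dexamethasone remains a hypothesis.

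Probe sets that name no single gene, which the gene comparison leaves out, held 24 past the threshold. The highest had a signal of 2.95 in medium and 245 with dexamethasone, at least 17.5-fold higher, and another rose 4.38-fold from 178. The 2 that fell most had log2 differences of -1.13 and -0.94.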

How the results depend on the processing

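The pseudocount of 16 and scaling to the hybridization controls were chosen only after the result was seen; the other alternatives were planned. Against 218 changed genes, 45 at least 2-fold changes and 4 lists, no filter gave 116 changed genes, with more genes tested, and the fit without trend gave 19, all at least 2-fold (17 rose, 2 fell); for the latter the cause was not tested. Between groups the labels match the arrays by replicate number only. The replicate 1 minus replicate 2 differences of the groups correlated at 0.0723 across genes and at 0.139 over the 2774 with a mean signal over 100. The hybridization controls were higher on replicate 1 in both groups, by 0.17 in medium and 0.19 with dexamethasone on the log2 scale. A replicate effect shared by the groups therefore stays possible. A replicate block gave 353 changed genes (169 rose, 184 fell), and the immediate-early list had an adjusted p of 0.0543 with it and Bcl2l1 one of 0.0309. Camera with an estimated correlation gave 0 lists and fry 0. Centring on array medians, which moved the median of all genes to -0.06, gave 254 changed genes, with 92 rises and 162 falls against 105 and 113. Scaling to the hybridization controls, which moved it to -0.46, gave 2553 changed genes (41 higher, 2512 lower) and 201 at least 2-fold (14 higher, 187 lower); it also turned the ribosomal list's mean to -0.29, Ncl to -0.085, Psma6 to -0.0742 and Tap2 to -0.0794, by the size of that shift. Leaving out an array gave 32 to 78 changed genes (44 without the first medium array, 32 without the second, 38 without the first dexamethasone array, 78 without the second), 25 to 39 at least 2-fold changes (26 without the second medium array, 25 without the first dexamethasone array) and 3 to 4 lists; the lone array of a group is then assumed to vary like the other group. Other alternatives gave 203 to 290 changed genes. All 218 genes kept their direction where tested, except 1 under the mean of a gene's probe sets and 13 under scaling to the hybridization controls. Leaving out an array cannot turn the direction of a gene whose groups do not overlap. The filter, the trend and the block leave its difference unchanged, so a direction kept in these alternatives is no separate evidence. All 54 named genes that passed kept their direction in the alternatives fixed beforehand for single genes, 13 stayed past the threshold in each of the 4 fits without an array and 10 in each alternative run for them (15, or 14 for the 10 genes too dim for the stricter filter); single genes were not run under the mean of a gene's probe sets or with probe sets in place of genes. The receptor-target and cholesterol lists passed in 15 of 17 alternatives each, the ribosomal list in 13 and the immediate-early list in 10. Named genes that had not passed gained 26 calls over the alternatives, 17 of them with scaling to the hybridization controls. Signal over background limits Usp18, Tnfsf11 and Gpr65, whose log2 differences were 2.65, 1.76 and 1.59 with the pseudocount of 16, against 4.31, 3.83 and 2.91.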

Other observations

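The genes described here were chosen only after their values were seen, as was the neighbour test that leaves out the first group of genes; the neighbour test over all genes was set down before its value was known, from a pair already noticed.

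Of the 218 changed genes, 168 were in none of the lists. Emb, which encodes the adhesion protein embigin, rose 2.64-fold from 166 ± 9.26 to 440 ± 12.6 (mean ± SD, n = 2), and Lmo4, a LIM-domain transcriptional regulator, rose 2.51-fold. Atp1b3, a subunit of the sodium pump, rose from 1428 to 3093, and Jak1, a kinase of cytokine receptors, rose 1.73-fold. Nfil3, a bZIP transcription factor, rose 2.38-fold from a dim signal of 24.0. Among the falls were Sox4, a transcription factor of early thymocytes, with a log2 difference of -0.62 ± 0.07, and Ntn1, which encodes netrin-1, with -1.04 ± 0.10. Msmo1, a sterol synthesis enzyme outside the cholesterol list, fell by 0.92 on the log2 scale.

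The Zfp36 family of mRNA decay proteins changed in opposite directions. Zfp36l2 rose from 927 ± 51.8 to 3311 ± 47.7, and its other probe sets had log2 differences of 2.58 and 1.63. Zfp36 fell from 138 ± 1.06 to 76.8 ± 0.212 and Zfp36l1 from 151 ± 29.7 to 86.8 ± 3.25. Of 5 MHC class II genes and chaperones, H2-Ab1 fell and the others did not pass, with log2 differences of -0.84 for H2-Ab1, -0.44 for H2-DMa, -0.41 for H2-Aa, -0.25 for Cd74 and -0.17 for H2-Eb1. All 5 belong to the list of macrophage, granulocyte and dendritic cell markers, of which 12 of 15 were lower at the deposited scaling (mean -0.20, camera adjusted p = 0.0887, and 0.0338 without the filter, in a range of 0.0338 to 0.742 over 17 alternatives).

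Eipr1, with its log2 difference of 3.04, lies next to Trappc12 in the reference gene order, which rose by 0.67, and Trappc12 lies next to Adi1, which rose by 1.06. The hypothesis that genes changed in the same direction may lie next to each other more often than chance was tested over 5490 of the 5582 genes. There were 9 same-direction pairs within 2 places, against a mean of 2.67 in 10000 random placements of the calls (one-sided permutation p = 0.001). The other pairs were Ddit4 and Anapc16, Ccnd3 and Bysl, Hnrnpab and Nhp2, Xrcc6 and Desi1, Pmm1 and Xrcc6, and Ecpas and Ptgr1. Without Adi1, Trappc12 and Eipr1, 6 pairs remained against a mean of 2.60 (one-sided permutation p = 0.0468), and the permutation p was 0.0594 when calls were placed among genes of like signal, in 10 groups, so the hypothesis stays open beyond the group that prompted it.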
